A study of Mus musculus with 6 samples.

How the data were processed

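RNA was measured in endothelial cells isolated from mouse retinas at postnatal day 7 after tamoxifen at postnatal day 1, on a mixed BL6/CD1 background. RNA was extracted with a column kit and libraries were made with an Illumina TruSeq RNA v2 kit, per the labels' protocols. Per the submitters' processing notes, STAR, DESeq2 and the mm10 genome were used, with no versions given. The counting tool and the annotation are not given in the sources used here. Both tables used covered the whole series. The first held the authors' deposited read counts per gene, whole numbers that had not been normalized, in 18 columns. The second held the authors' deposited comparison of the groups, with a mean normalized signal per gene, log2 fold changes and their standard errors, a test score, p-values and adjusted p-values, per the file headers.

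Groups were taken from the genotype label. Replicates were numbered in accession order, which pairs no samples. Sample titles begin with Lit38 (4 samples, 2 per group) or Lit40 (1 sample per group), called prefix 38 and prefix 40 here. These letters can be read as litter, which the labels do not state. The labels also do not state whether each sample came from 1 pup or from several, so p-values measure the spread between these samples. Each sample had 3 columns in the count table. All 3 held identical values in every one of 24421 genes, and each sample entered every test once, except in fits that say they used all 18 columns.

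The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM scaling, no covariate, genes kept by filterByExpr (minimum count 10, minimum total 15) and a Benjamini-Hochberg adjusted p under 0.05. This left 14362 genes. CPM values were scaled by TMM. The standard error of a log2 fold change was its size divided by the square root of the F statistic. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives. A set of 46 gene lists for endothelial biology, other retinal cell types and sample quality was fixed before the data were examined. The 43 lists with at least 5 tested members were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, which asks whether a list's genes move one way on balance. Symbols were matched through a synonym for 11 list members, and 18 had no gene in the table. Coordinates are from GENCODE M21 (mm10). Figures were drawn with matplotlib 3.10.9.

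Genes to be named were fixed before the data were examined: Smad4; Angpt2, Tek, Eng, Acvrl1, Id1, Id3, Smad6, Smad7, Klf2 and Klf4 whatever their value; genes past the main threshold ranked by fold and by p; up to 4 members of each list with the smallest p; and the most abundant genes of quality lists. No gene passed the main threshold, so the DESeq2 calls were named after their values were seen. Some genes that these rules would name are not reported here. The level of a list relative to the endothelial list was the mean log2 CPM of its members minus that of the endothelial list, leaving out shared genes, tested by an exact two-sided permutation of the 6 samples.

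Total counts ran from 2233360 to 23164952 per sample. A count of 3 corresponded to 1.39 CPM in Smad4-iECKO replicate 2 and to 0.123 to 0.239 CPM in the other libraries, and such floors cover counting error only. The tests were tried on simulated data drawn from the real means, depths and dispersions of the Smad4-iECKO and Smad4f/f libraries, with 200 genes changed, 50 at each fold. On 14129 genes edgeR recovered 0 of 50 genes changed 2-fold, 16 of 50 changed 4-fold, 43 of 50 changed 8-fold and 48 of 50 changed 16-fold, with 5 false calls. On 14362 genes DESeq2 recovered 9, 27, 47 and 50 of 50 at these folds, with 43 false calls. On 14129 genes voom with sample quality weights recovered 0, 16, 41 and 46 of 50, with 4 false calls. Genes were drawn independently around a single mean per gene, so variation shared by genes across libraries was not simulated. These counts need not hold for the real libraries.

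Alternatives fixed beforehand were other scalings, filters and thresholds, DESeq2, limma-voom with and without sample quality weights, robust dispersion, the title prefix as a block, a rod photoreceptor covariate, removal of sex-linked and Y chromosome genes, thinning to the smallest library, prefix 38 alone and leaving out each replicate. Those planned for a table without raw counts did not apply. Added after the data were seen were an endothelial covariate, scaling to the endothelial list, another edgeR dispersion option, fits on all 18 columns and further DESeq2 designs.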

Results

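Bulk RNA-seq was carried out on endothelial cells isolated from mouse retinas at postnatal day 7, from pups that had received tamoxifen at postnatal day 1. The 3 Smad4-iECKO samples carried floxed Smad4 and Cdh5-CreERT2, a tamoxifen-inducible Cre recombinase driven by an endothelial promoter, and the 3 Smad4f/f samples carried the floxed gene without Cre. Smad4 encodes the shared mediator of BMP and TGF-beta signalling. The count table held 18 columns, 3 for each of the 6 samples. The 3 columns of a sample did not differ in any of the 24421 genes, so each sample was counted as 1 (n = 3 per group). Total counts were 12633018, 23164952 and 13747917 in Smad4f/f replicates 1, 2 and 3. They were 17677696, 2233360 and 12680649 in Smad4-iECKO replicates 1, 2 and 3. The shallow Smad4-iECKO replicate 2 stood apart, with correlations of log2 CPM of 0.790 to 0.829 with the other libraries, against 0.898 to 0.972 among those. These correlations are across genes, which are not independent replicates.

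Smad4 transcripts from the targeted gene (chromosome 18, 73639009 to 73703780, mm10) were present at similar levels in both groups. Smad4f/f replicates 1, 2 and 3 held 109.5, 152.9 and 157.5 CPM, and Smad4-iECKO replicates 1, 2 and 3 held 128.2, 93.9 and 133.9 CPM. The means were 140.0 ± 26.5 and 118.7 ± 21.7 CPM (SD, n = 3 each), a log2 fold change of -0.24 with a standard error of 0.29 (edgeR, unadjusted p = 0.441). The labels do not say which exons are floxed, and a count per gene includes reads from exons that remain after deletion, as well as reads from cells in which Cre is not active. The gene count of Smad4 therefore does not check the genotype labels.

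The comparison of Smad4-iECKO with Smad4f/f asked which transcripts of the isolated cells differ after loss of Smad4 from the endothelium. Thbs1, Angpt2 and Esm1 were higher in every Smad4-iECKO library than in any Smad4f/f library. Thbs1 encodes the matrix glycoprotein thrombospondin, and Esm1 is a tip cell marker. Thbs1 was at 65.9 ± 12.997 against 11.4 ± 3.81 CPM, a 5.80-fold difference. Angpt2, the angiopoietin that antagonises the TIE2 receptor, was at 101.3 ± 22.2 against 21.4 ± 15.1 CPM. Esm1 was at 39.0 ± 2.45 against 7.79 ± 5.97 CPM. Slc16a1, the lactate and ketone transporter MCT1 of barrier endothelium, was lower, at 36.7 ± 8.95 against 241.5 ± 163.0 CPM. None of these passed the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment over 14362 genes. By edgeR 0 genes were higher and 0 lower, and the smallest adjusted p was 0.864 (Thbs1). An unadjusted p under 0.05 was reached by 188 genes, where chance alone gives about 718.

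DESeq2, run as an alternative, called 12 genes, 9 higher and 3 lower, with 425 genes at an unadjusted p under 0.05. These genes were chosen for naming after their values were seen. The higher ones were Thbs1 (log2 fold change 2.54, standard error 0.40, DESeq2 adjusted p = 2.03e-06), Eda2r, Ptpn7, Phlda3, Mir3086, Itgb4, Angpt2 (2.25, standard error 0.51, DESeq2 adjusted p = 0.0207), Esm1 and Cdkn1a. The lower ones included Slc16a1 and Crispld1. Eda2r, a TNF receptor family member, was at 13.9 ± 8.93 CPM in Smad4-iECKO and 0.761 ± 0.231 CPM in Smad4f/f. Cdkn1a, the cell cycle inhibitor p21, was at 52.9 ± 25.8 against 12.6 ± 3.96 CPM. The integrin subunit Itgb4 was at 29.3 ± 9.91 against 6.30 ± 3.19 CPM. Thbs1 and Eda2r passed DESeq2's threshold without each of the 6 libraries in turn, and Ptpn7 in 5 of those 6 fits. Slc16a1 passed in 3, Angpt2, Esm1, Cdkn1a, Phlda3 and Crispld1 in 2 each, and Itgb4 and Mir3086 in 1 each. Mir3086 was not among the genes tested by edgeR, and had no adjusted p without Smad4-iECKO replicate 2. On the simulated data DESeq2 made 43 false calls. The DESeq2 count was 35 without Smad4f/f replicate 1, 16 without Smad4f/f replicate 2 and 4 without Smad4f/f replicate 3. It was 8 without Smad4-iECKO replicate 1, 10 without Smad4-iECKO replicate 2 and 4 without Smad4-iECKO replicate 3.

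**Figure D1:**
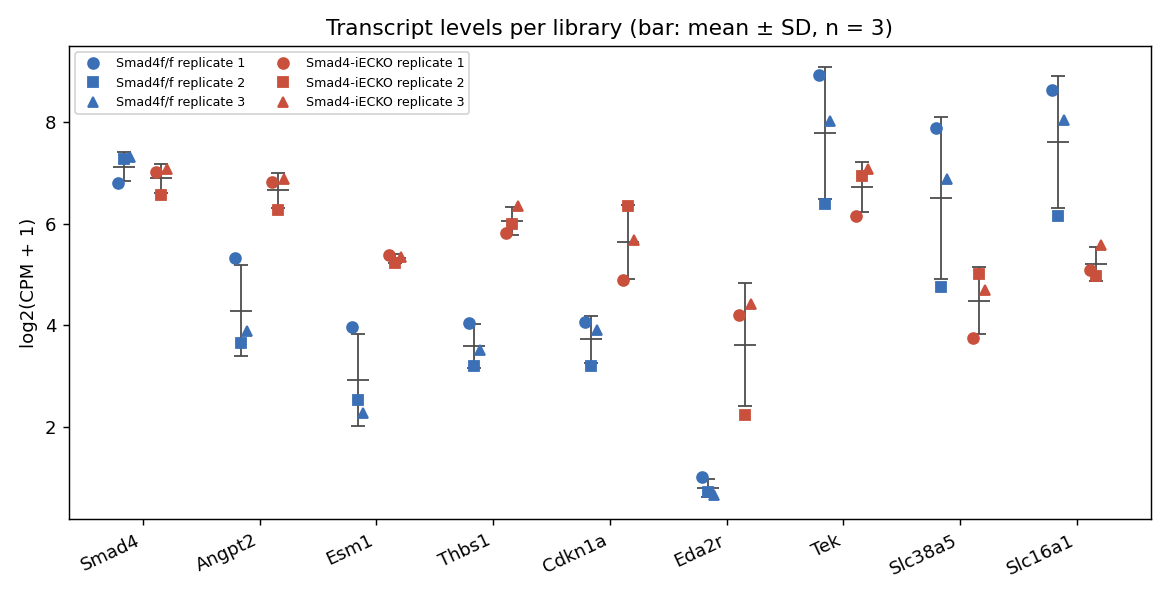
Levels of 9 genes in each library, as log2(CPM + 1), in Smad4f/f (blue) and Smad4-iECKO (red), with marker shape for the replicate and bars for mean ± SD (n = 3). Angpt2, Esm1, Thbs1, Cdkn1a and Eda2r lie higher in all 3 Smad4-iECKO libraries, Slc16a1 lower in all 3, and the Smad4 values of the groups overlap.

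Among the endothelial gene lists, tip cell, permeability and matrix genes ranked higher in Smad4-iECKO than other genes did. Of 32 tested tip cell genes, 22 had positive log2 fold changes (median 0.37). Their camera adjusted p was 2.75e-09 with a preset correlation, and the adjusted p was 0.703 with an estimated correlation. Beside Angpt2 and Esm1 these included Igfbp3, at 582.9 ± 179.9 against 168.4 ± 119.0 CPM. Apln, the ligand apelin, was at 365.8 ± 42.7 against 108.3 ± 91.5 CPM. Of 19 genes of permeable and immature endothelium, 13 were positive (median 0.49, adjusted p = 1.52e-06, and adjusted p = 0.703 with an estimated correlation). Plvap, which forms the diaphragms of fenestrae, was at 64.2 ± 31.0 against 14.6 ± 8.49 CPM. Of 58 basement membrane and matrix genes, 45 were positive (median 0.41, adjusted p = 6.64e-11, and adjusted p = 0.703 with an estimated correlation). Col15a1 was at 349.9 ± 244.8 against 107.8 ± 43.8 CPM, highest in Smad4-iECKO replicate 2 (623.3 CPM), and the collagen-modifying enzyme P4ha2 at 12.7 ± 1.52 against 4.94 ± 0.632 CPM. The integrin and focal adhesion list ranked higher too (21 of 28 positive, adjusted p = 0.000534, and adjusted p = 0.861 with an estimated correlation). So did the shear stress list, which holds Thbs1, Angpt2 and Ctgf (21 of 35 positive, adjusted p = 0.00978, and adjusted p = 0.861 with an estimated correlation). No member passed the test over all genes. Adjusted over the list alone, 2 tip cell genes (Angpt2, Esm1) and 3 permeability genes (Esm1, Plvap, Igfbp3) did. So did 1 matrix gene (Thbs1), 1 integrin gene (Itgb4) and 2 shear stress genes (Thbs1, Angpt2). Angpt2, Esm1 and Thbs1 each count in more than 1 list, so these lists are not independent of each other. Adjustment over a list alone, here and below, does not correct for the number of lists. In the 4 libraries with title prefix 38 (2 per group), the tip cell, matrix, integrin and shear stress lists ranked on the lower side without passing the threshold (adjusted p = 0.658, 0.442, 0.442 and 0.347).

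Capillary and barrier genes had the lowest median log2 fold change of the 43 tested lists, with 31 of 37 negative (median -0.91, camera adjusted p = 3.05e-11, and adjusted p = 0.703 with an estimated correlation). The endothelial junction and identity list was lower as well, though not called (26 of 37 negative, median -0.35). With scaling to that list the barrier median was -0.50. Slc22a8, an organic anion transporter of neural endothelium, was at 6.68 ± 2.65 in Smad4-iECKO against 34.3 ± 24.1 CPM. Spock2 was at 231.2 ± 118.5 against 1001.3 ± 659.8 CPM, and Itm2a at 69.8 ± 15.0 against 263.4 ± 214.5 CPM. Slc38a5, an amino acid transporter of the venous list, was at 22.8 ± 9.53 against 125.7 ± 104.2 CPM. Slc16a1 alone of the barrier list passed when adjusted over the list alone. The WNT and beta-catenin barrier list, with Apcdd1 (103.6 ± 34.5 against 295.0 ± 181.1 CPM), was not called (14 of 21 negative, adjusted p = 0.105). Smad4f/f replicate 2, which held the lowest share of endothelial transcripts, lay close to the Smad4-iECKO libraries in Slc22a8, Spock2, Itm2a and Slc38a5. Its Spock2 level was 254.3 CPM, against 1504.6 and 1245.0 CPM in Smad4f/f replicates 1 and 3. In the pair with title prefix 40 (1 library per group, no test), the log2 ratio of Smad4-iECKO to Smad4f/f was above 0 for Slc22a8 (0.17), Spock2 (0.52), Slc38a5 (0.25) and Apcdd1 (0.36). The endothelial list's mean log2 CPM was 5.59 in the Smad4f/f and 7.05 in the Smad4-iECKO library of this pair, for which the ratios were not corrected.

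The share of endothelial transcripts varied more within the groups than between them. Transcripts of the endothelial junction and identity list took 1.45%, 0.309% and 0.828% of counts in Smad4f/f replicates 1, 2 and 3. They took 0.498%, 0.823% and 0.770% in Smad4-iECKO replicates 1, 2 and 3. Rod photoreceptor transcripts took 1.13% to 2.34% of counts in all libraries, more than the endothelial list in every library except Smad4f/f replicate 1. Neural retina thus contributed RNA to all libraries, and a difference between the groups need not come from endothelial cells. Each list was therefore also taken relative to the endothelial list within a library, a comparison chosen after the data were seen. At the same endothelial level, the tip cell list was at -0.43 ± 0.19 in Smad4f/f and 0.38 ± 0.11 in Smad4-iECKO (log2, mean ± SD, n = 3). The permeability list was at -1.59 ± 0.29 and -0.76 ± 0.17, and the matrix list at -1.003 ± 0.366 and -0.354 ± 0.0821. These 3 lists were higher in all 3 Smad4-iECKO libraries. The capillary and barrier list was at -0.67 ± 0.11 and -1.37 ± 0.27, lower in all 3. For each of these the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows, with an adjusted p of 1 over 42 lists. The 4 lists without overlap are about as many as chance gives (10%).

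**Figure D2:**
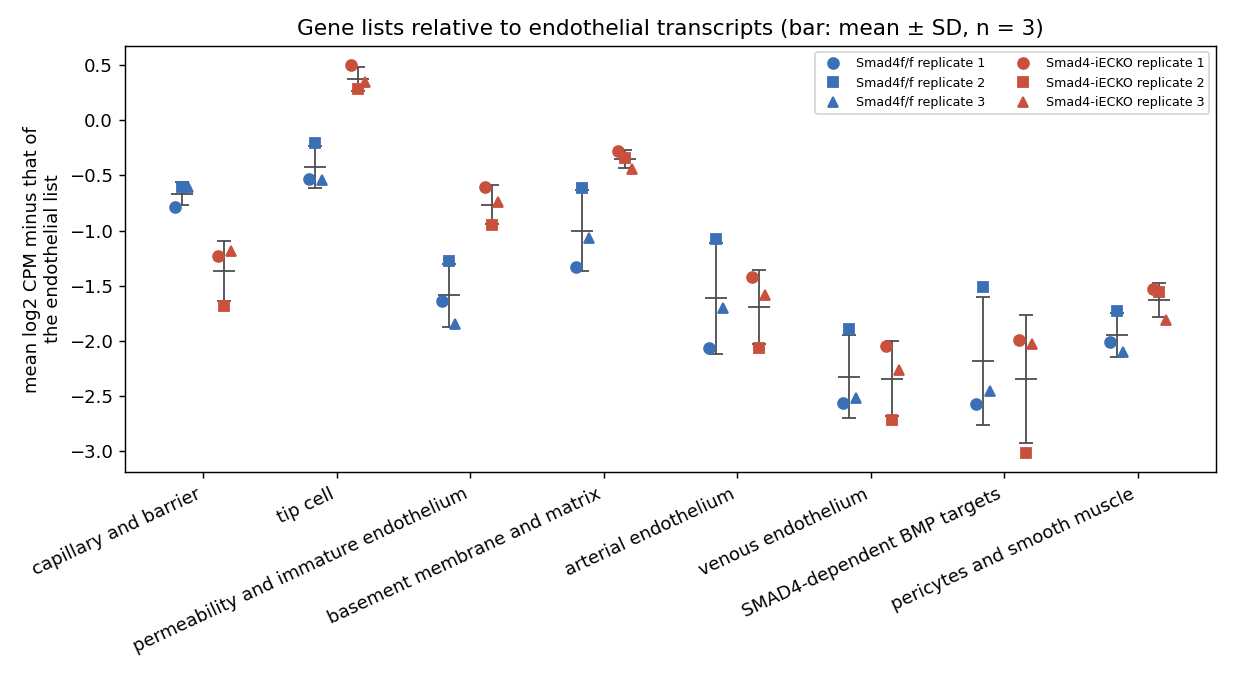
Mean log2 CPM of 8 gene lists minus that of the endothelial list in each library, in Smad4f/f (blue) and Smad4-iECKO (red), with bars for mean ± SD (n = 3). The tip cell, permeability and matrix lists lie higher and the barrier list lower in all 3 Smad4-iECKO libraries, while the arterial, venous, BMP target and pericyte lists overlap.

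Targets of BMP signalling did not move together, and the list of BMP and TGF-beta components was not called. Of 33 tested components, 22 were positive and 11 negative (median 0.053, camera adjusted p = 0.187). Of 23 tested SMAD4-dependent BMP targets, 10 were positive and 13 negative (median -0.23, camera adjusted p = 0.861). Without Smad4f/f replicate 1 the list ranked higher and passed (adjusted p = 0.0404). Cdkn1a was the 1 that passed when adjusted over the list alone. Id1, a direct BMP target, was at 39.6 ± 33.5 CPM in Smad4-iECKO and 60.8 ± 43.3 CPM in Smad4f/f, and Id3 at 107.1 ± 79.0 and 102.8 ± 79.5 CPM. The inhibitory SMADs were at 30.6 ± 26.0 and 13.5 ± 4.41 CPM for Smad6 and 57.2 ± 29.2 and 43.0 ± 9.51 CPM for Smad7, with no call for either. Smad6 was highest in Smad4-iECKO replicate 2 (59.96 CPM). The BMP receptor genes Acvrl1 (139.3 ± 45.8 and 120.4 ± 81.9 CPM) and Eng (376.5 ± 124.8 and 285.9 ± 163.3 CPM) differed by less than the spread between replicates. So did the flow-induced transcription factors Klf2 (36.3 ± 7.91 and 43.9 ± 30.3 CPM) and Klf4 (21.8 ± 10.3 and 24.1 ± 17.6 CPM). Gja4, the arterial gap junction protein connexin 37, was at 32.3 ± 11.98 against 84.7 ± 53.4 CPM, with overlapping groups. Tek, the angiopoietin receptor TIE2, was at 108.0 ± 33.4 against 275.6 ± 201.9 CPM, also overlapping. In the prefix 40 pair the log2 ratio was above 0 for Id1 (1.76), Klf2 (1.26), Klf4 (0.77), Gja4 (0.30) and Tek (0.55), all lower on average. The endothelial list's mean log2 CPM also differed in this pair, at 5.59 in Smad4f/f replicate 2 and 7.05 in Smad4-iECKO replicate 2. These ratios were not corrected for that. The arterial (13 of 33 positive, adjusted p = 0.631), venous (11 of 23, adjusted p = 0.625), Notch (11 of 19, adjusted p = 0.0897), VEGF (5 of 11, adjusted p = 0.190) and angiopoietin (4 of 8, adjusted p = 0.229) lists were not called. In the VEGF list the median was -0.016 although camera placed it on the higher side.

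Hypoxia and glycolysis genes ranked higher in Smad4-iECKO, with 32 of 36 positive (median 0.26, camera adjusted p = 9.10e-07, and adjusted p = 0.498 with an estimated correlation). Vegfa, also in the astrocyte list, was at 318.2 ± 69.1 against 156.3 ± 25.6 CPM. The oxygen-sensing hydroxylase Egln3 was at 6.91 ± 1.71 against 2.18 ± 0.301 CPM and the hexokinase gene Hk2 at 33.4 ± 3.41 against 16.3 ± 6.86 CPM. Each was higher in all 3 libraries. The placental growth factor gene Pgf was at 8.34 ± 2.18 against 2.79 ± 1.30 CPM. Oxidative phosphorylation genes ranked lower (39 of 41 negative, median -0.45, adjusted p = 4.18e-08, and adjusted p = 0.703 with an estimated correlation). Cox8a was at 78.6 ± 17.6 against 129.2 ± 18.7 CPM and Sdhd at 42.3 ± 12.96 against 72.1 ± 17.97 CPM. All 56 ribosomal protein genes were negative (median -0.66, adjusted p = 3.39e-11, and adjusted p = 0.861 with an estimated correlation). Smad4f/f replicate 1 held 1.94% of its counts in that list, against 0.662% to 0.923% in the other 5 libraries. Reads of ribosomal protein genes can be shared with their processed pseudogenes.

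Among lists for other cell types, microglia and macrophage genes ranked higher in Smad4-iECKO (23 of 25 positive, median 0.67, camera adjusted p = 4.18e-08, and adjusted p = 0.703 with an estimated correlation). The list's mean log2 CPM overlapped, at 1.91, 0.89 and 1.54 in Smad4f/f and 2.14, 1.22 and 2.49 in Smad4-iECKO (replicates 1, 2 and 3). Relative to the endothelial list the groups overlapped too (exact permutation p = 0.4). Itgam was at 8.82 ± 3.32 against 2.29 ± 0.984 CPM. Laptm5 was at 18.6 ± 8.88 against 7.004 ± 1.59 CPM and the complement gene C1qc at 11.3 ± 3.91 against 4.19 ± 2.16 CPM. The fibroblast list (9 of 13 positive, adjusted p = 0.00978) and the astrocyte list (8 of 15, adjusted p = 0.0166) also ranked higher, each with an adjusted p of 0.703 with an estimated correlation. Their leading genes, Col1a2 (129.8 ± 142.8 against 23.0 ± 4.84 CPM) and Pax2 (10.4 ± 7.76 against 2.53 ± 0.705 CPM), were highest in single libraries, Smad4-iECKO replicate 2 for Col1a2 (294.7 CPM) and replicate 3 for Pax2 (19.3 CPM). The immediate early list was called as well (21 of 32 positive, adjusted p = 0.00978, and adjusted p = 0.703 with an estimated correlation), with Dusp1 at 61.7 ± 41.4 against 22.2 ± 6.54 CPM. The mesenchymal transition list (14 of 24 positive) had an adjusted p of 0.0265, and adjusted p = 0.861 with an estimated correlation. The interferon list (24 of 34 positive) had an adjusted p of 0.0374, and adjusted p = 0.934 with an estimated correlation. The rod (adjusted p = 0.407), cone (0.383), Mueller glia (0.847), ganglion cell (0.861), amacrine and horizontal cell (0.758), bipolar cell (0.879), progenitor (0.450), pericyte (0.321), lymphocyte and neutrophil (0.975), erythroid (0.0711) and pigment epithelium (0.203) lists were not called.

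In all, 15 of 43 tested lists passed with the preset correlation, 12 higher and 3 lower, and 0 with an estimated correlation (smallest adjusted p 0.498) or with fry (smallest adjusted p 0.344). The count was 29 without Smad4f/f replicate 1. When each library was left out in turn, the barrier, microglia, oxidative phosphorylation and hypoxia lists passed in all 6 fits with the preset correlation of 0.01. Their estimated correlations were higher, at 0.64, 0.20, 0.30 and 0.026 in that order. These fits also share most of their libraries. The other 11 lists missed the threshold or turned in at least 1 fit, with adjusted p up to 0.211 for the tip cell and matrix lists and 0.164 for the permeability list. The remaining lists were not called: PI3K, AKT and FOXO1 (adjusted p = 0.321), endothelial identity (0.224), guidance cues (0.105), apelin, chemokine and GPCR signalling (0.987), inflammatory adhesion (0.625), G1/S (0.861) and G2/M (0.204) cell cycle genes, cholesterol synthesis (0.204) and sex-linked transcripts (0.407). The platelet and lens lists had 3 tested members each and the mitochondrially encoded list none, too few for a test.

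The authors' deposited table of the same comparison held 1905 genes with an adjusted p under 0.05, 1095 higher and 810 lower in Smad4-iECKO, among 14225 genes with an adjusted p. In the authors' deposited table Thbs1 had a log2 fold change of 2.41 (adjusted p = 4.33e-50), Angpt2 of 1.92 (adjusted p = 1.54e-12), Slc16a1 of -2.18 (adjusted p = 5.27e-13) and Smad4 of -0.22 (adjusted p = 0.188). Of those 1905 genes, 1850 were tested by edgeR on 6 samples, and all 1850 had the same sign there. An unadjusted edgeR p under 0.05 was found for 187 of them, and 662 had groups that did not overlap. Both comparisons rest on the same counts, so shared signs and groups without overlap are not independent support. Across all tested genes, 763 (5.31%) had groups that did not overlap, where chance gives 10%. The authors' calls shared with edgeR numbered 0, and those shared with DESeq2 on 6 samples numbered 12.

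**Figure D3:**
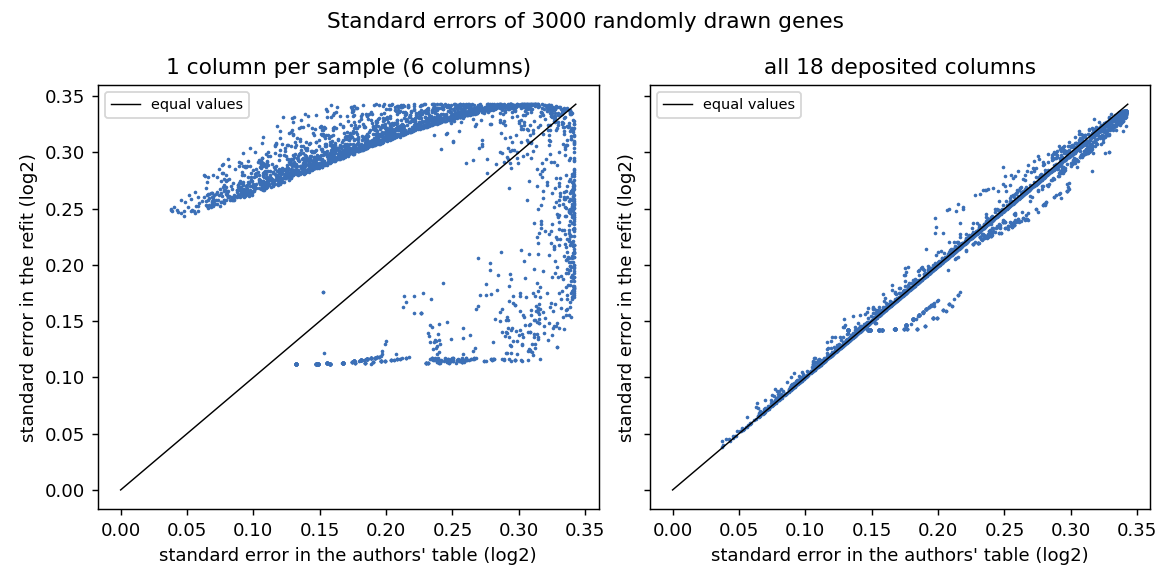
Standard errors of log2 fold changes of 3000 randomly drawn genes in the authors' table (x axis) and in a DESeq2 refit with a coefficient prior (y axis, both log2 units), with 1 column per sample (left) and with all 18 deposited columns (right). The line marks equal values; the median ratio of refit to table was 1.38 on the left and 0.997 on the right.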

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

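The alternatives on all 18 columns, with the endothelial list as covariate or scale, with edgeR's legacy option off and the further DESeq2 designs were chosen after seeing the data. Smad4 kept its direction and stayed short of the threshold in every alternative, with log2 fold changes from -0.48 (scaled to the endothelial list) to -0.040 (prefix 38 alone). edgeR called 0 genes in either direction on 6 samples or fewer under every scaling, filter, threshold, covariate and left-out replicate that was run; limma-voom also called 0. Calls came from DESeq2 (9 higher, 3 lower, 12 shared with the authors' table), voom with sample quality weights (8 higher, 8 shared), DESeq2 with the prefix as a replicate block (11 higher, 6 lower, 17 shared), DESeq2 with the endothelial covariate (37 higher, 11 lower, 44 shared) and DESeq2 without the shallow library (6 higher, 4 lower, 10 shared). With all 18 columns taken as samples, edgeR called 493 higher and 332 lower (816 shared) and DESeq2 1348 higher and 887 lower (1778 shared). The prefix as a replicate block in edgeR left 0 calls and 15 lists. With this block 303 genes had an unadjusted p under 0.05, against 188 in the main test. Deviations from group means correlated at -0.154 to 0.170 between libraries of the same prefix. Between libraries of different prefixes the range was -0.158 to 0.185. Deviations from a group mean cancel within the group, so these correlations cannot decide whether the prefix pairs libraries. Lists past the threshold numbered 15, 27 with voom quality weights, 0 with an estimated correlation and 0 with fry, and 12 to 29 when each replicate was left out. Scaling to the endothelial list moved the median log2 fold change of all genes from -0.017 to -0.18, and edgeR's count at an unadjusted p under 0.05 from 188 to 54; without Smad4f/f replicate 2 that count was 303. The cause of these differences was not tested, apart from the smaller number of samples in left-out fits and the repeated columns. The depth of 2233360 counts limits the low genes of Smad4-iECKO replicate 2.

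The direction turned in these cases, given as log2 fold changes for genes and camera adjusted p for lists; the cause was not tested. With voom Id3 was -0.034 and Klf4 0.20, and with quality weights Id3 was -0.27, Smad7 -0.089, Klf2 0.0023 and Klf4 0.36. With the replicate block, Id3 was -0.061 in edgeR and -0.056 in DESeq2, where Klf4 was 0.0087. With the rod covariate Id3 was -0.28. In prefix 38 alone, Acvrl1 was -0.43, Id3 -1.16, Smad6 -0.025 and Smad7 -0.28, and the matrix (0.442), tip cell (0.658), integrin (0.442) and shear stress (0.347) lists turned. With each replicate left out in turn, the ranges were -0.011 to 0.74 for Eng, -0.20 to 0.84 for Acvrl1, -1.60 to 0.049 for Id1, -0.74 to 0.84 for Id3, -0.11 to 0.63 for Smad7, -0.67 to 0.39 for Klf2 and -0.60 to 0.61 for Klf4. Smad6 (0.21 to 1.56) and Col15a1 (0.96 to 2.05) kept their direction but moved by more than 1.5 times, as did many other named genes. The adjusted p ranged from 3.04e-09 to 0.569 for the shear stress, 3.74e-08 to 0.870 for the mesenchymal, 4.59e-10 to 0.569 for the interferon and 0.0404 to 0.888 for the BMP target list. Called lists that kept their direction but missed the threshold in at least 1 of these fits had a highest adjusted p of 0.211 (tip cell), 0.211 (matrix), 0.164 (permeability), 0.677 (integrins), 0.964 (ribosomal proteins), 0.749 (immediate early), 0.348 (fibroblasts) and 0.609 (astrocytes). The lists turned without Smad4f/f replicate 2 (shear stress, mesenchymal, interferon), without Smad4-iECKO replicate 3 (interferon, 0.376), and without Smad4f/f replicate 1 or Smad4-iECKO replicate 1 (BMP targets, 0.0404 and 0.358). DESeq2 without the shallow library gave Acvrl1 -0.018, Id3 -0.72, Smad7 -0.099 and Klf4 0.038. With the endothelial covariate Klf2 was 0.069 and Klf4 0.23 in edgeR and 0.075 and 0.23 in DESeq2, and with endothelial scaling 0.075 and 0.22. The BMP target list turned in these 3 fits (0.786, 0.670 and 0.998) and on 18 columns with DESeq2 (0.995). In the prefix 40 pair (1 against 1, no test) the log2 ratio also turned for Id1 (1.76), Klf2 (1.26), Klf4 (0.77), Tek (0.55), Gja4 (0.30), Slc38a5 (0.25), Slc22a8 (0.17), Spock2 (0.52) and Apcdd1 (0.36). The ratios of this pair were not corrected for its differing endothelial levels (mean log2 CPM 5.59 in Smad4f/f and 7.05 in Smad4-iECKO). The lists that were not called, apart from the BMP target list, and some of the named genes were not followed through the alternatives.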

Other observations

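Sex-linked transcripts showed that the libraries differed in sex composition within both groups. Smad4f/f replicate 3 held 3166 CPM of Xist and 0 CPM of the Y-linked Ddx3y. Smad4f/f replicate 1 and Smad4-iECKO replicates 1 and 2 held 6.39, 3.39 and 0 CPM of Xist with 187.6, 134.5 and 29.8 CPM of Ddx3y. Smad4f/f replicate 2 and Smad4-iECKO replicate 3 held both, with 1988 and 2017 CPM of Xist and 66.2 and 75.5 CPM of Ddx3y. RNA of more than 1 pup was therefore present in these libraries, by a route that the labels do not state. The precursor of ribosomal RNA, Rn45s, took 1.98% of counts in Smad4-iECKO replicate 2 and 0.077% to 0.373% in the other libraries.

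Apart from the second p53 list, whose prediction came first, and the DESeq2 and list counts over splits, the tests below were chosen after the result was seen. Several genes at the top of the comparison, Eda2r, Phlda3, Cdkn1a and Zmat3, are textbook targets of p53, the transcription factor of the DNA damage response. In a list of 18 such targets that was put together after these values were seen, 15 were positive (median 1.19), 9 with an unadjusted edgeR p under 0.05. In a second list, written down before its fold changes were seen, 25 were tested, 15 were positive and the median was 0.12, above 94.09% of 10000 expression-matched random lists. That is short of the level set beforehand for a response of the set, and above the level set for none. Tnfrsf10b was the single member at an unadjusted edgeR p under 0.05 (log2 fold change 1.14, standard error 0.49). The random lists drew genes singly, so the percentile ignores correlation between genes and does not measure the spread between samples. In mean log2 CPM of the first 18 genes, the lower of the other Smad4-iECKO libraries lay 0.70 above the highest Smad4f/f library without the shallow one. Those genes were picked on their values in all 6 libraries, so this does not exclude the shallow library. A candidate explanation is activity of the Cre recombinase, which the Smad4f/f samples lack, and another is loss of Smad4; 0 samples had Cre without the floxed gene, so these cannot be told apart.

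Barrier transcripts were lower and tip cell transcripts higher at the same level of endothelial transcripts in all 3 Smad4-iECKO libraries. The tip cell level minus the barrier level was 0.24 ± 0.17 in Smad4f/f and 1.75 ± 0.21 in Smad4-iECKO (log2, mean ± SD, n = 3), with a gap of 1.15 between the groups, and of 1.15 without Smad4-iECKO replicate 2. Both lists were singled out because their groups did not overlap, so a gap had to appear. Smad4-iECKO replicates 1 and 3, which were not shallow, lay at 1.73 and 1.54, against 0.062 to 0.39 in Smad4f/f. Their endothelial shares (0.498% and 0.770% of counts) lay inside the Smad4f/f range (0.309% to 1.45%). The lists were picked on their values in all 6 libraries, so these values cannot exclude the shallow library or a difference in endothelial yield. Chance stays open, since 4 of 42 lists without overlap are about as many as chance gives (10%). The pericyte list (23 tested, 7 of its 25 members also in other lists, with Rgs5 at 490.7 ± 139.8 and 750.1 ± 650.7 CPM in Smad4-iECKO and Smad4f/f) was 0.31 higher relative to endothelial transcripts, against 0.81 for the tip cell list. Its members went both ways (12 positive and 11 negative log2 fold changes, SD 0.57 between members), so more pericytes stay open. The fibroblast and perivascular stroma list was 0.49 higher (SD 0.59 in Smad4f/f and 0.29 in Smad4-iECKO), against 0.65 for the matrix list, with which 9 tip cell genes are shared, so more stroma stays open too. Loss of Smad4, Cre itself and a delay of vessel maturation for another reason also stay open, and no test here separates them.

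The authors' deposited table called 1905 genes where edgeR on 6 samples called 0 and DESeq2 called 12. A DESeq2 fit with a coefficient prior on all 18 columns gave standard errors whose median ratio to the table's was 0.997, with 84.9% within 5%, fold changes that correlated at 0.993 across genes, and 2178 calls. The same fit on 6 columns gave a ratio of 1.38 and 10 calls. This is consistent with the identical columns having been counted as separate samples, which makes standard errors too small for 3 samples per group.

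The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. edgeR called 0 genes in the real split and at most 0 in the others (all 10 splits as large). DESeq2 called 12 in the real split and at most 32 in the others (3 of 10 as large). Camera called 15 lists in the real split and at most 34 in the others (7 of 10 as large). On simulated data without variation shared by genes, DESeq2 made 43 false calls. A count of 32 therefore does not by itself point to a structure of the samples other than genotype. The split that put Smad4f/f replicates 1 and 3 with Smad4-iECKO replicate 2 gave the 32 calls. Those libraries held the highest shares of endothelial transcripts (1.45%, 0.828% and 0.823% of counts). Smad4f/f replicate 2 and Smad4-iECKO replicates 1 and 3 held 0.309%, 0.498% and 0.770%. This split therefore also separated the libraries by endothelial share, and whether that share gave the calls was not tested.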
